A study of Mus musculus with 21 samples.

How the data were processed

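RNA of ATDC5 cells was measured in 21 samples: Ctrl, C3, LPA, Scrmbl and siYap1/Wwtr1 with 3 each, and Glass, 55 kPa and 5 kPa with 2 each. The tables hold a signal per gene and library, which per the submitters' processing notes and the file headers is a read count divided by 1 DESeq2 size factor per library. The authors also deposited DESeq2 log2 fold changes and adjusted p-values for C3, LPA and siYap1/Wwtr1 against their controls and for 55 kPa and 5 kPa against Glass. The reads were placed on mm10 per the submitters' processing notes, from stranded poly(A) libraries. The aligner, the counting tool, whether strand was used in counting, the annotation and the version of DESeq2 are not given in the sources used here. Genes that overlap or lie antisense to each other, and near-identical paralogs, are therefore uncertain.

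Each table was normalised separately. Whole reads were recovered from the signal by finding the size factor that makes every value whole (tolerance 0.02, 100.0% of values whole in each library). For siYap1/Wwtr1 2 the size factor, 1.005, was close to 1. The recovered reads were then rescaled by median-of-ratios jointly over the libraries of each experiment. Libraries that recur in several tables held equal reads. Of 47729 gene identifiers 47224 had a symbol, 505 had none, and 419 had no position in GENCODE M21 (GRCm38), the source of the coordinates given here. The table for 5 kPa lists 18541 genes, so the substrate comparisons rest on 18538 genes shared by all tables. Glass 1 and Glass 2 were equal in all of them and were used as 1 library. Depth was 53.6 to 120.1 M reads per library. At these depths a gene with 1 to 3 reads in a group has no usable fold change, and such genes are given as levels.

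Values were compared as log2(value + 1) with limma 3.58.1 (R 4.3.3, trend and robust empirical Bayes). Genes with a value of at least 1 in at least 3 libraries (2 for the substrates) were tested. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The addition of 1 makes fold changes of weakly expressed genes too small. The plan, written before the data were examined, named edgeR for read counts and limma for normalised values, and limma was used since the tables hold normalised values. C3, LPA and Ctrl shared 1 fit, as did the 3 substrates. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these samples. Mean and SD are of normalised read counts, and the SE is that of the log2 fold change.

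In the plan 26 gene lists were fixed: YAP/TAZ targets, SRF/MRTF cytoskeletal, cartilage, hypertrophic chondrocyte, fibrous matrix and tendon, cell cycle, focal adhesion, Rho GTPase pathway, LPA receptor and lipid phosphatase, immediate early, TGF-beta and BMP response, Wnt response, interferon response, NF-kB inflammatory, cholesterol synthesis, glycolysis and hypoxia, stress response (UPR and ATF4), p53 target, sulfated proteoglycan synthesis, adipocyte, osteoblast, skeletal muscle, endothelial and macrophage marker, mitochondrially encoded and cytosolic ribosomal protein genes. They were tested with camera at a preset correlation of 0.01 and again with a correlation estimated from the data, adjusted over the lists of each comparison (7 comparisons, 182 list tests). Named genes were Yap1, Wwtr1, Ccn1, Ccn2, Ankrd1, Sox9, Col2a1 and Acan, and the 8 largest rises and 8 largest falls past the threshold. These needed an average log2 value of at least 2 and replicates of the groups that did not overlap, and predicted genes, pseudogenes and unnamed identifiers were left out. Up to 4 members of each list with the smallest p-value in a comparison were added.

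The main fits held no replicate number in any experiment, as the plan fixed. Pairing by the replicate numbers in the labels was checked by correlating each library's deviations from its group mean. In the knockdown experiment the same-numbered pairs correlated at 0.114, 0.175 and 0.188, and the paired result is given for the count of genes, for the genes described most closely and where pairing changed the call of a named gene. Alternatives fixed in the plan were no filter on low values, an estimated correlation, quantile normalisation, replicate number in the model, leaving out each library, all samples in 1 fit, only the 2 groups compared, and a pseudocount of 0.1. EdgeR 4.0.16 (quasi-likelihood, on the recovered reads) and Glass counted as 2 libraries were added after the data were seen. Genes shared between comparisons were counted against n1 × n2 / N and tested with Fisher's exact test.

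The whole procedure was tested on simulated data with 100 genes changed per fold. With limma 69, 73 and 52% of 2-fold changes and 97, 92 and 96% of 4-fold changes were recovered in the designs of C3, LPA and siYap1/Wwtr1, and 9.86, 8.37 and 8.33% of calls were false. In the substrate designs, simulated without replicate number in the model, 0% of either were recovered. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.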

Results

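Messenger RNA of ATDC5 cells was sequenced in 21 samples from 3 experiments. ATDC5 is a mouse line of cartilage precursor cells, grown here in a chemically defined medium that leads them toward chondrocytes. In the first experiment, cells were collected at day 3 without a drug (Ctrl), with C3 transferase (C3), a bacterial enzyme that inactivates Rho GTPases, or with lysophosphatidic acid (LPA), a lipid that activates Rho through its receptors, with 3 samples per group. In the second, cells were collected 5 days after transfection with a non-targeting siRNA (Scrmbl) or with siRNAs against Yap1 and Wwtr1 (siYap1/Wwtr1), with 3 samples per group. Wwtr1 encodes TAZ, and YAP and TAZ are transcriptional coactivators that respond to cell tension. In the third, cells were seeded sparsely on fibronectin-coated glass or polyacrylamide gels of 55 kPa or 5 kPa and collected at day 2, with 2 samples per group. The 2 Glass samples held the same value in all of 18541 genes, so Glass counts as 1 library here and the series as 20 distinct libraries.

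Depth was 53.6 to 120.1 M reads assigned to genes per library. By group it was 79.9 to 81.8 M in Ctrl, 53.6 to 81.9 M in C3, 62.8 to 87.7 M in LPA, 90.8 to 117.8 M in Scrmbl and 93.7 to 117.5 M in siYap1/Wwtr1. The Glass library held 75.9 M reads, the 55 kPa libraries 68.8 and 120.1 M, and the 5 kPa libraries 71.6 and 106.3 M.

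Both siRNA targets fell in the knockdown. The normalised read count of Yap1 (ENSMUSG00000053110, mm10 chromosome 9, 7931999 to 8004596) was 16560, 15200 and 14940 in Scrmbl 1, 2 and 3, and 2741, 2538 and 2506 in siYap1/Wwtr1 1, 2 and 3, a log2 fold change of -2.58 ± 0.10 (SE, adjusted p = 4.47e-06). Wwtr1 (ENSMUSG00000027803, chromosome 3, 57455649 to 57575910) was at 13300, 11240 and 16160 in Scrmbl and at 3788, 3065 and 4723 in siYap1/Wwtr1, a log2 fold change of -1.82 ± 0.18 (adjusted p = 0.000392). Yap1 in the other libraries was 11210, 10110 and 11810 in Ctrl, 10110, 8817 and 9428 in C3, 11990, 11650 and 11740 in LPA, 10290 on Glass, 7889 and 12760 on 55 kPa, and 8003 and 11760 on 5 kPa. Wwtr1 was at 13030, 11380 and 16610 in Ctrl, 11210, 11430 and 12150 in C3, 13210, 13470 and 12430 in LPA, 5766 on Glass, 7488 and 12800 on 55 kPa, and 7423 and 18850 on 5 kPa. Neither gene passed the test in C3 vs Ctrl (Yap1 -0.22 ± 0.08, adjusted p = 0.0695, and Wwtr1 -0.22 ± 0.11, adjusted p = 0.194), but without Ctrl 2 both did, at 0.0177 and 0.0201, and Yap1 did under quantile scaling, at 0.0147.

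**Figure D1:**
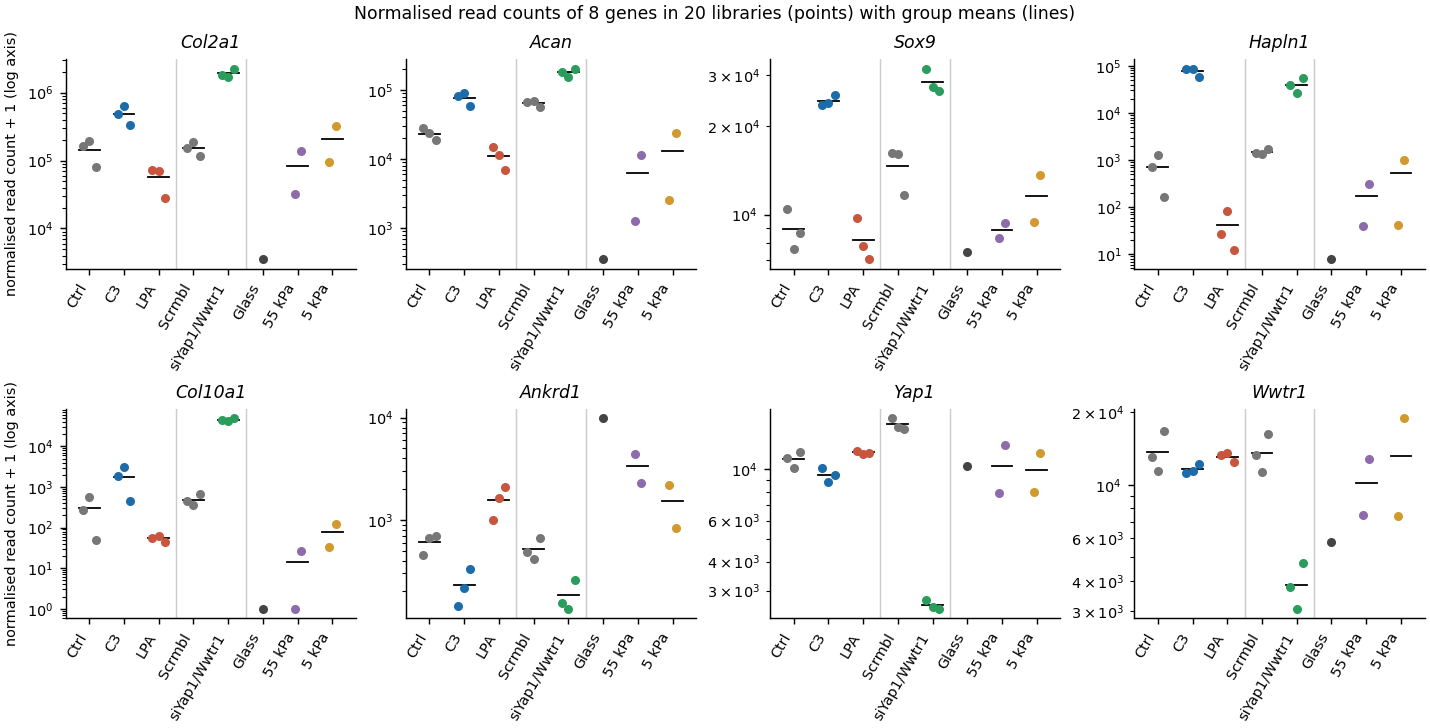
Normalised read count plus 1 of 8 genes on a log axis in 20 libraries (points) with the mean of each group (lines); counts were normalised within each experiment, and grey lines part the 3 experiments. Col2a1 averaged 151500 in Scrmbl and 1931000 in siYap1/Wwtr1, and it was at 3530 on Glass and at 94060 and 318900 on 5 kPa.

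Does blocking Rho move these cells toward cartilage? Compared with untreated cells, C3 changed 5158 of 23475 tested genes (limma, adjusted p under 0.05), 3035 higher and 2123 lower, and 2028 of them by at least 2-fold. Sox9 (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760), the master transcription factor of cartilage, rose from 8933 ± 1434 to 24400 ± 982.6 normalised reads (mean ± SD, n = 3 libraries each), a log2 fold change of 1.46 ± 0.13 (SE, adjusted p = 1.81e-06). Acan (ENSMUSG00000030607, chromosome 7, 79053483 to 79115099), the core protein of the large cartilage proteoglycan, rose from 23350 ± 4540 to 76830 ± 15530, by 1.72 ± 0.31 (adjusted p = 0.00681). Col2a1 (ENSMUSG00000022483, chromosome 15, 97975602 to 98004695), the chain of the main cartilage collagen, was 1.78 ± 0.51 higher, at 485800 ± 152200 against 145300 ± 57690, and did not pass the test (adjusted p = 0.0539, but 0.0424 under quantile scaling, 0.0338 by edgeR and 0.0432 with only the 2 groups in the fit). The largest rises were in genes nearly silent in Ctrl. Spink5, a protease inhibitor of skin, rose from 8.385 ± 7.035 to 5197 ± 1231 reads (9.42 ± 0.61, adjusted p = 1.07e-06). Ackr2, a chemokine scavenger, rose by 9.22 ± 0.35 (adjusted p = 9.86e-10), and Cytl1, a secreted protein of chondrocytes, by 9.22 ± 1.28 (adjusted p = 0.00299). Of the largest falls, Kcnj2, an inward-rectifier potassium channel, fell from 727.5 ± 103.1 to 133.3 ± 40.84 (-2.48 ± 0.22, adjusted p = 1.87e-06). Others, such as Itprid1 (26.1 to 3.189 reads) and Nanos3 (9.942 to 0.6382), were near the floor of detection. The p-values measure only the spread between these 3 samples per group. Quantile scaling moved the median fold change of all genes by -0.104 and turned the split of changed genes to 2606 higher and 3063 lower.

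By gene list, 19 of 25 cartilage genes rose and 0 fell in C3 (20 rose adjusted over the list alone, median log2 fold change 1.78, camera adjusted p = 8.37e-13, and 0.404 with an estimated correlation). They included Sox6 (3.09 ± 0.13) and Fgfr3 (2.56 ± 0.12), regulators of growth-plate cells, and Chst11 (1.16 ± 0.11), which sulfates chondroitin. Of 26 SRF/MRTF cytoskeletal genes, which report on actin tension, 20 fell and 1 rose (22 and 1 adjusted over the list alone, median -0.819, adjusted p = 1.57e-11, and 0.404 with an estimated correlation). The actin-binding Cnn2 fell from 27950 ± 2934 to 10040 ± 2279 reads (adjusted p = 8.55e-06), and Fhl2 (-0.93) and Filip1l (-0.88) fell too. Fhl1 was the 1 that rose (3.29 ± 0.13, adjusted p = 1.52e-09). Of 28 cell cycle genes, 23 fell and 0 rose (the same counts adjusted over the list alone, median -0.697, adjusted p = 4.22e-12, and 0.404 with an estimated correlation), among them Ccnb2 (-0.85), Cenpe (-0.82) and Ccna2 (-0.81). Immediate early genes, the first transcribed after a stimulus, rose in 8 of 17 and fell in 0 (9 and 1 adjusted over the list alone, adjusted p = 0.000206, and 0.404 with an estimated correlation). They were led by Nr4a1 at 3.67 ± 0.14, Fosb at 2.72 and Fos at 2.13. NF-kB inflammatory genes rose in 11 of 19 and fell in 1 (13 and 1 adjusted over the list alone, adjusted p = 0.000176, and 0.404 with an estimated correlation). The neutrophil chemokine Cxcl1 rose by 3.69 ± 0.30 (adjusted p = 6.68e-06) and Relb by 0.79. Sulfated proteoglycan synthesis genes rose in 9 of 19 and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.000242, and 0.404 with an estimated correlation). They included the sulfate transporter Slc26a2 (1.48) and the chain-starting enzyme Xylt1 (2.14). LPA receptor and lipid phosphatase genes rose in 4 of 9 and fell in 1 (5 and 1 adjusted over the list alone, adjusted p = 0.0173, and 0.404 with an estimated correlation). Lpar4 stood at 2.63 ± 0.19, Enpp2, which makes LPA, at 1.58, and Lpar6 at -0.82.

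Smaller list shifts came with C3 too. Of 28 cytosolic ribosomal protein genes 4 fell and 0 rose (the same adjusted over the list alone), with a median of -0.233 (adjusted p = 9.09e-06, 0.164 with all samples in one fit, and 0.647 with an estimated correlation). None of 24 interferon response genes passed the test (0 adjusted over the list alone as well), at a median of -0.502 (adjusted p = 0.0342, and 0.918 with an estimated correlation). That interferon call was lost without Ctrl 1 (0.326), Ctrl 2 (0.391) or C3 3 (0.184), under quantile scaling (0.155) and by edgeR (0.122). YAP/TAZ targets went both ways, 6 of 22 up and 6 down (adjusted p = 0.92), with a median and a test below 0 and a mean above it. Ankrd1 (ENSMUSG00000024803, chromosome 19, 36111961 to 36120099), a direct YAP/TAZ target, fell from 606.2 ± 130.2 to 229.3 ± 94.48 (-1.46 ± 0.35, adjusted p = 0.0181), a call lost without Ctrl 2 (0.0936), Ctrl 3 (0.0859) or C3 2 (0.0695). The matrix regulator Ccn1 fell by 0.63 ± 0.18 (adjusted p = 0.0307), a call lost without Ctrl 2 (0.158), Ctrl 3 (0.143), C3 1 (0.069) or C3 2 (0.0762), whereas its relative Ccn2 rose by 0.52 ± 0.11 (adjusted p = 0.00402). The YAP/TAZ targets Nt5e (1.12) and Crim1 (1.06) rose and Nuak2 (-0.88) fell.

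Lists without a camera call still held genes that C3 changed. Fibrous matrix and tendon genes rose in 5 of 23 and fell in 10 (adjusted p = 0.177), with the collagen VI chains Col6a3 up by 2.57 ± 0.12 and Col6a1 by 1.61 and Thbs1 down by -0.93. Focal adhesion genes rose in 5 of 27 and fell in 11 (adjusted p = 0.177, but 0.0335 without Ctrl 2), including the collagen-binding integrin Itga11, which fell from 5480 to 2705 reads, and the laminin-binding Itga6, which rose by 1.26. Rho GTPase pathway genes rose in 6 of 27 and fell in 6 (adjusted p = 0.898), Rhob by 1.81 and Rnd3 by -0.90. TGF-beta and BMP response genes rose in 5 and fell in 4 of 17 (adjusted p = 0.757), Wnt response genes rose in 7 and fell in 6 of 18 (adjusted p = 0.757), with Notum (3.00) and Lgr6 (1.62) up and the stem-cell marker Lgr5 (-1.52) down. Target genes of p53 rose in 7 and fell in 3 of 15 (adjusted p = 0.177, but 0.0464 with all samples in one fit), and the cell cycle inhibitor Cdkn1a rose by 3.75 ± 0.52 (adjusted p = 0.00295). Hypertrophic chondrocyte genes rose in 5 and fell in 2 of 16 (adjusted p = 0.209), cholesterol synthesis genes in 1 and 5 of 20 (0.292, but 0.0304 without Ctrl 1), glycolysis and hypoxia genes in 3 and 0 of 25 (0.563) and stress response genes in 2 and 3 of 20 (0.943). Marker genes of other cell types rose and fell in 2 and 0 of 9 for adipocytes (0.543), 1 and 1 of 9 for osteoblasts (0.943), 3 and 1 of 8 for skeletal muscle (0.757), 3 and 0 of 9 for endothelium (0.126, but 0.0053 by edgeR and 0.00517 with all samples in one fit) and 0 and 0 of 6 for macrophages (0.292). The mean and the median of a list differed in sign for the fibrous, Rho and TGF-beta lists. None of the 13 mitochondrially encoded genes was measured in these tables.

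LPA was the opposite treatment, promoting Rho activity. It changed 1168 of 23475 genes (limma), 424 higher and 744 lower, 410 of them by at least 2-fold. That count depended on single libraries: it was 529 without Ctrl 1, 655 without Ctrl 2, 2619 without Ctrl 3, 557 without LPA 2 and 469 without LPA 3. With all samples in one fit it was 111. Across genes Ctrl 3 correlated at r = 0.983 with LPA 1 and with LPA 2, about as with Ctrl 1 (0.983) and Ctrl 2 (0.982). The macrophage elastase gene Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499) rose from 375.6 ± 195.9 to 9818 ± 2101 reads (n = 3 each), by 4.86 ± 0.45 (adjusted p = 0.00205). The stromelysin gene Mmp10 rose from 2.483 ± 2.843 to 62.3 ± 17.56 reads (adjusted p = 0.00119). The lipoprotein gene Apob rose by 3.53 ± 0.45 (adjusted p = 0.000702) and the retinol dehydrogenase gene Rdh8 by 3.10 ± 0.26 (adjusted p = 3e-05). The microfibril-associated gene Adamtsl2 fell from 259.7 ± 78.76 to 16.52 ± 9.816 (-4.07 ± 0.43, adjusted p = 0.000304). The interferon-inducible Ifi205 fell by -3.88 ± 0.52 (adjusted p = 0.00145) and the neuropeptide gene Npy from 26.4 ± 8.425 to 1.282 ± 1.147 reads (adjusted p = 0.000749). Trim30d, at 34.15 reads on average in Ctrl, and Hif3a, at 11.8, were at 0 in every LPA library. Col2a1 was at 56670 ± 24800 reads, -1.39 ± 0.51 against Ctrl, and did not pass the test (adjusted p = 0.208). Acan was at 11080 ± 3994 (-1.13 ± 0.31, adjusted p = 0.0968, and 0.0439 without LPA 1) and Sox9 at 8200 ± 1404 (-0.13 ± 0.13, adjusted p = 0.654). Ankrd1 was at 1573 ± 542.7 (1.33 ± 0.35, adjusted p = 0.0727, and past the threshold without LPA 1 at 0.0229, by edgeR at 0.0425 and with only the 2 groups in the fit at 0.0487). Ccn1 (0.01 ± 0.18, adjusted p = 0.993), Yap1 (0.10 ± 0.08, adjusted p = 0.575) and Wwtr1 (-0.05 ± 0.11, adjusted p = 0.861) did not pass, nor did Ccn2 (-0.30 ± 0.11, adjusted p = 0.156, but 0.0256 without Ctrl 3).

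Among the lists, interferon response genes had the lowest median in LPA, -2.67 over 24 members (camera adjusted p = 8.14e-23, and 0.327 with an estimated correlation). Over all genes only Ifit2 passed, falling from 6076 ± 1612 to 3174 ± 271.8 (-0.90 ± 0.17, adjusted p = 0.012, but 0.104 without Ctrl 2 and 0.0554 without LPA 3), while all 24 fell adjusted over the list alone. The antiviral gene Mx2 was at 4203 ± 2649 reads in Ctrl and 347.9 ± 192.1 in LPA (adjusted p = 0.0675), and the list stood at 1.82 and 1.80 in Ctrl 1 and Ctrl 2 but -0.35 in Ctrl 3, as a median log2 deviation from the experiment mean. Of 20 cholesterol synthesis genes 15 fell and 0 rose (17 adjusted over the list alone, median -0.564, adjusted p = 9.32e-18, and 0.327 with an estimated correlation). They included Insig1, a sterol-sensing regulator, which fell from 18270 ± 2003 to 9196 ± 487.5 (-0.99 ± 0.09, adjusted p = 3.63e-05), Cyp51 (-0.81 ± 0.10), Msmo1 (-0.77) and Mvk (-0.83). Of 25 cartilage genes 5 fell and 0 rose (14 adjusted over the list alone, median -1.13, adjusted p = 1.28e-11, and 0.327 with an estimated correlation), Matn3 by -1.98 ± 0.31 (adjusted p = 0.00321). NF-kB inflammatory genes rose in 5 of 19 and fell in 0 (9 adjusted over the list alone, adjusted p = 0.000161, and 0.388 with an estimated correlation). The adhesion molecule Vcam1 rose from 670.7 ± 39.19 to 1538 ± 111.6 reads (adjusted p = 0.000107), Tnfaip3 by 1.29 and Nfkbia by 0.83. Wnt response genes rose in 1 and fell in 5 of 18 (1 and 6 adjusted over the list alone, adjusted p = 0.00177, and 0.327 with an estimated correlation). They included the R-spondin receptors Lgr6 (-2.23 ± 0.13, adjusted p = 2.88e-06) and Lgr5 (-1.13). Focal adhesion genes rose in 3 of 27 and fell in 0 (9 and 1 adjusted over the list alone, adjusted p = 0.000351, and 0.531 with an estimated correlation), Tln2 by 0.75 and the fibronectin receptor chain Itga5 by 0.52. Hypertrophic chondrocyte genes rose in 2 and fell in 4 of 16 (2 and 7 adjusted over the list alone, adjusted p = 0.0115, and 0.385 with an estimated correlation). Mmp9 stood at 2.34 ± 0.19 and the pyrophosphate transporter Ank at -0.82.

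Several LPA list calls rested on single libraries. SRF/MRTF cytoskeletal genes rose in 3 and fell in 1 of 26 (8 and 2 adjusted over the list alone, adjusted p = 0.0117, and 0.639 with an estimated correlation). That call was lost without Ctrl 1 (0.246) or LPA 3 (0.0988). Rho GTPase pathway genes rose in 1 and fell in 1 of 27 (4 and 1 adjusted over the list alone, adjusted p = 0.0189, and 0.531 with an estimated correlation). It was lost without Ctrl 1 (0.0915), Ctrl 2 (0.0665) or LPA 3 (0.0518) and with all samples in one fit (0.0714). Fibrous matrix and tendon genes rose in 1 and fell in 4 of 23 (2 and 7 adjusted over the list alone, adjusted p = 0.0051, and 0.531 with an estimated correlation), Scx by -0.86. The call was lost without LPA 3 (0.0861) and under quantile scaling (0.389). Glycolysis and hypoxia genes rose in 2 of 25 (2 adjusted over the list alone, adjusted p = 0.000407, and 0.559 with an estimated correlation), Vegfa by 0.70. The call was lost without Ctrl 3 (0.0609) or LPA 1 (0.301). Osteoblast marker genes fell in 3 of 9 (3 adjusted over the list alone, adjusted p = 0.0359, and 0.327 with an estimated correlation), with Dmp1 at -3.36 ± 0.34 and Dlx5 at -1.59 ± 0.14. The call was lost without Ctrl 1 (0.0613), Ctrl 3 (0.0904) or LPA 2 (0.0722) and with replicate number in the model (0.0589). Sulfated proteoglycan synthesis genes fell in 3 and rose in 0 of 19 (4 and 1 adjusted over the list alone, adjusted p = 0.00218, 0.205 with all samples in one fit, and 0.385 with an estimated correlation). No call was made for cell cycle genes (adjusted p = 0.367, but 0.0497 without Ctrl 3 and 0.0412 without LPA 1), ribosomal protein genes (0.163, but 3.5e-08 without Ctrl 2, 0.0204 without LPA 2 and 0.0365 under quantile scaling) or stress response genes (0.183, but 0.018 without Ctrl 3 and 0.0204 without LPA 2), none of whose members passed over all genes. YAP/TAZ targets rose in 2, among them Tgfb2 by 0.94 ± 0.10, and fell in 3 of 22 (adjusted p = 0.269), and TGF-beta and BMP response genes rose in 1 and fell in 3 of 17 (0.289), Id1 by -1.21. LPA receptor and lipid phosphatase genes fell in 2 of 9 (0.46) and immediate early genes in 2 of 17 (0.901), and in both the median and the mean differed in sign. Also without a call were p53 target genes (0 of 15, 0.46) and markers of adipocytes (1 of 9 up, 0.572), skeletal muscle (2 of 8 down, 0.149, but 0.028 by edgeR and 0.0397 with all samples in one fit), endothelium (0 of 9, 0.367) and macrophages (0 of 6, 0.973).

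**Figure D2:**
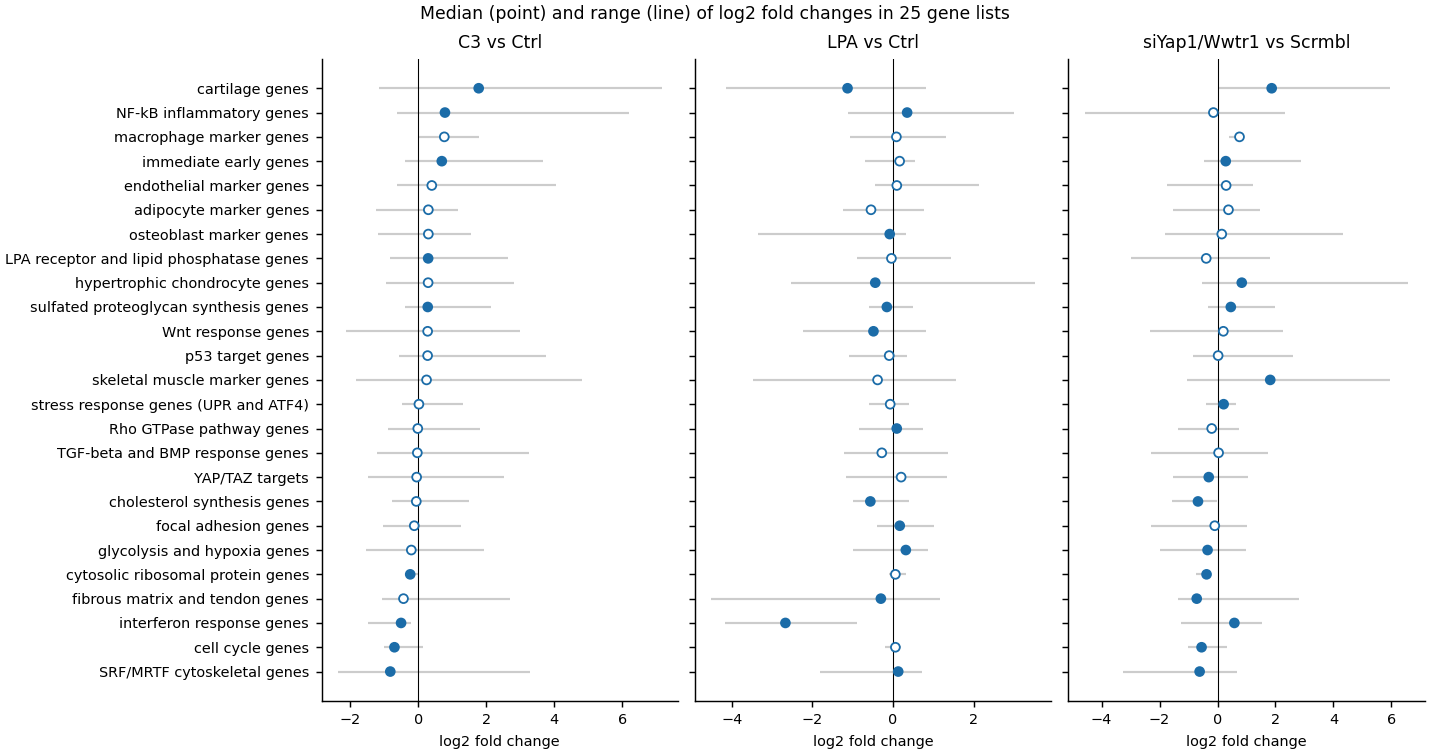
Median (point) and range (line) of the log2 fold changes in 25 gene lists for C3 vs Ctrl, LPA vs Ctrl and siYap1/Wwtr1 vs Scrmbl; filled points mark a camera adjusted p under 0.05 with the preset correlation. The cartilage median was 1.78 in C3, -1.13 in LPA and 1.87 in siYap1/Wwtr1, and no list kept its call with an estimated correlation.

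Set directly against each other, C3 and LPA differed in 6235 of 23475 genes (limma), 3586 higher and 2649 lower in C3, 2471 of them by at least 2-fold. Quantile scaling moved the median of all genes by -0.117 and gave 2981 higher and 3964 lower. Hapln1 (ENSMUSG00000021613, chromosome 13, 89539796 to 89611652), which links aggrecan to hyaluronan, averaged 77080 ± 15630 reads in C3 and 39.92 ± 38.25 in LPA (11.31 ± 0.97, adjusted p = 0.000264). Col2a1 was 3.17 ± 0.51 (adjusted p = 0.00479), Acan 2.84 ± 0.31 (adjusted p = 0.00043) and Sox9 1.59 ± 0.13 (adjusted p = 6.06e-07) higher in C3. Mmp12 was lower in C3 (-5.36 ± 0.45, adjusted p = 0.000115), and so were the adhesion gene Cdh15 (-5.64 ± 0.79, adjusted p = 0.00124) and Ankrd1 (-2.79 ± 0.35, adjusted p = 0.000407). Ccn2 was higher (0.82 ± 0.11, adjusted p = 9.13e-05), Yap1 lower (-0.32 ± 0.08, adjusted p = 0.0101, but 0.0662 without C3 2) and Wwtr1 not past the test (-0.17 ± 0.11, adjusted p = 0.318). Ccn1 was lower (-0.64 ± 0.18, adjusted p = 0.0241), a call lost without C3 1 (0.0518), C3 2 (0.0613), LPA 2 (0.082) or LPA 3 (0.0881).

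The list differences followed the separate treatments in part. Cartilage genes were higher in C3 in 22 of 25 and lower in 0 (23 adjusted over the list alone, median 2.84, adjusted p = 3.47e-18, and 0.298 with an estimated correlation). SRF/MRTF genes were lower in 22 and higher in 1 of 26 (24 and 1 adjusted over the list alone, median -0.973, adjusted p = 1.55e-12, and 0.33 with an estimated correlation), for example Tpm1 (-1.24) and Myh9 (-1.06). Cell cycle genes were lower in 23 and higher in 2 of 28 (adjusted p = 5.61e-11, and 0.33 with an estimated correlation), and ribosomal protein genes lower in 14 of 28 (23 adjusted over the list alone, adjusted p = 3.82e-07, 0.0694 with all samples in one fit, and 0.362 with an estimated correlation). Interferon response genes were higher in 6 of 24 (18 adjusted over the list alone, adjusted p = 1.55e-07, and 0.362 with an estimated correlation), cholesterol synthesis genes in 11 of 20 (14 adjusted over the list alone, adjusted p = 3.39e-06, and 0.362 with an estimated correlation) and sulfated proteoglycan synthesis genes in 14 of 19, with 1 lower (adjusted p = 2.6e-06, and 0.298 with an estimated correlation). Focal adhesion genes were lower in 14 and higher in 3 of 27 (17 and 4 adjusted over the list alone, adjusted p = 0.000336, and 0.362 with an estimated correlation). Immediate early genes were higher in 9 and lower in 2 of 17 (adjusted p = 0.0011, and 0.362 with an estimated correlation), LPA receptor and lipid phosphatase genes in 6 and 1 of 9 (adjusted p = 0.00321, and 0.298 with an estimated correlation) and hypertrophic chondrocyte genes in 9 and 3 of 16 (10 and 3 adjusted over the list alone, adjusted p = 0.0139, and 0.33 with an estimated correlation). Glycolysis and hypoxia genes were higher in 2 and lower in 7 of 25 (adjusted p = 0.0132, and 0.577 with an estimated correlation), a call lost without C3 3 (0.0633) or LPA 1 (0.139), under quantile scaling (0.0611) and by edgeR (0.102). YAP/TAZ targets were higher in 8 and lower in 10 of 22 (adjusted p = 0.344), and endothelial markers higher in 3 of 9 (adjusted p = 0.164, but 0.0414 by edgeR and 0.0219 with all samples in one fit). In both of these the median was below 0 and the mean above it. Wnt response genes were higher in 8 and lower in 4 of 18 (adjusted p = 0.122, but 0.0188 by edgeR and 0.0278 with all samples in one fit), and p53 target genes in 6 and 1 of 15 (adjusted p = 0.0819, but 0.0257 with all samples in one fit).

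C3 and LPA were each compared with the same 3 Ctrl libraries, which cannot be split into independent sets of 2, so part of any overlap may come from those shared controls. Of 23475 genes, 584 changed in both. Higher in both were 146 (54.8 expected from n1 × n2 / N), lower in both 182 (67.3), higher in C3 and lower in LPA 190 (96.2), and lower in C3 and higher in LPA 66 (38.3). Among the 584, 56.2% changed the same way (Fisher's exact test, two-sided, p = 2.87e-05, genes not being independent). The log2 fold changes correlated across genes at r = 0.169 with a covariance of 0.105, and 100 simulated draws of unchanged groups against the same controls gave a median r of 0.524 (-0.623 to 0.921), a median covariance of 0.101 (-0.0976 to 0.385) and no gene changed in both. The observed r and covariance lay inside these ranges, which were too wide to part shared controls from shared responses. The 584 genes changed in both lay outside, as unchanged groups gave at most 0. Every library was drawn anew, controls included, without a treatment effect. The draws therefore cannot show what part of the 584 came from shared controls. The correlation was 0.257 without Ctrl 1 and 0.263 without Ctrl 3. The shared count was 270 without Ctrl 1, 357 without Ctrl 2, 1235 without Ctrl 3 (66.8% the same way), 313 without LPA 2 and 269 without LPA 3. It was 351 with only the 2 groups in each fit (Fisher p = 0.00101), 1334 with replicate number in the model (Fisher p = 0.0498) and 32 with all samples in one fit, where the test did not pass (Fisher p = 0.128).

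Does losing YAP and TAZ release cartilage genes as well? Of 23216 tested genes 2127 changed (limma), 1227 higher and 900 lower, 1225 of them by at least 2-fold. The count was 1153 without Scrmbl 1, and it was 6260 when replicate number was added to the model as a pair. With pairs 2905 genes (46.4%) were higher, against 57.7% without pairs, so most changed genes were then lower. Col2a1 rose from 151500 ± 35730 to 1931000 ± 290300 reads (n = 3 each), 12.9-fold (3.69 ± 0.18, adjusted p = 9.66e-06). Col10a1 (ENSMUSG00000039462, chromosome 10, 34389981 to 34397085), the collagen of hypertrophic chondrocytes, rose from 489.2 ± 155.8 to 45830 ± 3287 (6.59 ± 0.20, adjusted p = 1.14e-06), and Ibsp, a bone matrix sialoprotein, from 436.5 ± 28.64 to 40600 ± 9209 (6.51 ± 0.16, adjusted p = 3.53e-07). Acan rose by 1.49 ± 0.13 (adjusted p = 0.000212) and Sox9 from 14630 ± 2602 to 28350 ± 2763 (0.97 ± 0.15, adjusted p = 0.00397). The kinesin gene Kif12 rose from 1.355 ± 1.203 to 269 ± 58.97 reads (adjusted p = 6.86e-05), and Cytl1 by 6.04 ± 0.61 (adjusted p = 0.000624). Serpina1b, at 171.7 ± 153.3 reads in the knockdown, and its near-identical neighbours Serpina1d (96.06) and Serpina1a (93.53) were at 0 in every Scrmbl library. The sialic acid receptor gene Siglecg fell from 1474 ± 444.6 to 75.7 ± 33.1 (-4.33 ± 0.38, adjusted p = 0.000257) and the arginase gene Arg1 from 204.6 ± 65.29 to 10.12 ± 4.083 (-4.24 ± 0.40, adjusted p = 0.000312). Casp14 and Cxcl5 were at 27.09 and 23.22 reads on average in Scrmbl and at 0 in every knockdown library. Ankrd1 fell from 523.0 ± 131.7 to 182.8 ± 67.23 (-1.54 ± 0.29, adjusted p = 0.0103). Ccn1 was at -0.79 ± 0.28 (adjusted p = 0.133, but 1.65e-05 with pairs and 0.0247 without siYap1/Wwtr1 3) and Ccn2 at 0.37 ± 0.29 (adjusted p = 0.516, but 0.00101 with pairs). With pairs, adjusted p was 0.0131 for Col2a1, 2.96e-10 for Col10a1, 9.63e-13 for Ibsp, 0.000213 for Acan, 1.98e-06 for Sox9, 2.38e-07 for Kif12, 7.56e-09 for Cytl1, 8.2e-10 for Siglecg, 3.77e-07 for Arg1, 8.07e-06 for Ankrd1, 8.85e-11 for Yap1 and 1.24e-09 for Wwtr1. Of 119 named genes in this comparison 94 had a call without pairs, and 92 of those kept it with pairs, while Mymk (0.0972) and Irf7 (0.237) lost theirs. Another 12 had no call either way. The 13 that gained one were Ccn1, Ccn2, Vwf (0.00119), Cd68 (0.0083), Cebpa (0.00801), Herpud1 (0.00207), Btg2 (0.00568), Plpp1 (0.00343), Rpl7 (0.000722), Rps4x (0.000202), Aurkb (3.66e-05), Eda2r (0.00574) and Lpar3 (0.0116).

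In the knockdown 21 of 25 cartilage genes rose and 0 fell (22 adjusted over the list alone, median 1.87, adjusted p = 5.49e-27, and 0.233 with an estimated correlation), including Hapln1 (4.68 ± 0.24), Col11a2 (4.26 ± 0.20) and Fgfr3 (2.72). Hypertrophic chondrocyte genes rose in 7 of 16 and fell in 0 (the same adjusted over the list alone, adjusted p = 1.68e-08, and 0.233 with an estimated correlation), Panx3 by 4.40 ± 0.21 and the transcription factor Mef2c by 2.42. Sulfated proteoglycan synthesis genes rose in 8 of 19 and fell in 0 (12 adjusted over the list alone, adjusted p = 4.91e-08, and 0.268 with an estimated correlation), Xylt1 by 1.97 and Slc26a2 by 1.83. SRF/MRTF genes fell in 19 of 26 and rose in 0 (23 and 1 adjusted over the list alone, median -0.618, adjusted p = 2.11e-15, and 0.268 with an estimated correlation), among them the smooth muscle actin gene Acta2 (-1.70 ± 0.16) and tropomyosin gene Tpm1 (-1.52 ± 0.11). Cholesterol synthesis genes fell in 11 of 20 and rose in 0 (15 adjusted over the list alone, median -0.675, adjusted p = 5.1e-10, and 0.316 with an estimated correlation), Idi1 by -1.57 ± 0.24 and Fdps by -1.39. Fibrous matrix and tendon genes rose in 4 and fell in 12 of 23 (5 and 16 adjusted over the list alone, adjusted p = 0.00108, and 0.316 with an estimated correlation), with Fmod up by 2.32 and Postn and Thbs2 down by -1.28 and -1.38. Immediate early genes rose in 5 of 17 and fell in 0 (6 adjusted over the list alone, adjusted p = 0.00802, and 0.316 with an estimated correlation). Cell cycle genes fell in 3 of 28 and rose in 0 (9 adjusted over the list alone, adjusted p = 0.000983, and 0.538 with an estimated correlation). Skeletal muscle marker genes rose in 3 of 6 (3 adjusted over the list alone, adjusted p = 0.0167, and 0.268 with an estimated correlation), Tnnt3 by 2.56 ± 0.24. The targets of YAP/TAZ fell in 7 and rose in 1 of 22 (9 and 2 adjusted over the list alone, median -0.303, adjusted p = 0.0146, and 0.316 with an estimated correlation), Amotl2 by -1.13 ± 0.11 (adjusted p = 0.000335), with Nt5e the 1 that rose (1.06). This call was lost without siYap1/Wwtr1 2 (0.0571).

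Other knockdown list calls were lost when 1 library was left out. For interferon response genes, 1 rose and 1 fell of 24 (2 and 1 adjusted over the list alone, adjusted p = 0.00302, and 0.538 with an estimated correlation). It was lost without siYap1/Wwtr1 1 (0.104) or siYap1/Wwtr1 2 (0.067) and with all samples in one fit (0.0608). For ribosomal protein genes, 0 of 28 passed (0 adjusted over the list alone, median -0.379, adjusted p = 0.000983, and 0.538 with an estimated correlation). That was lost without Scrmbl 2 (0.0774) or siYap1/Wwtr1 1 (0.229). Glycolysis and hypoxia genes rose in 3 and fell in 5 of 25 (4 and 10 adjusted over the list alone, adjusted p = 0.0304, and 0.544 with an estimated correlation), Egln3 by -1.99. This was lost without Scrmbl 2 (0.203) or siYap1/Wwtr1 3 (0.206), by edgeR (0.0703) and with all samples in one fit (0.18). Stress response genes rose in 3 and fell in 0 of 20 (the same adjusted over the list alone, adjusted p = 0.0376, and 0.538 with an estimated correlation). This was lost without Scrmbl 2 (0.166), siYap1/Wwtr1 2 (0.0565) or siYap1/Wwtr1 3 (0.156), under quantile scaling (0.0625), by edgeR (0.149) and with all samples in one fit (0.131). Lists without a call were focal adhesion genes, with 1 up and 5 down of 27 (adjusted p = 0.0871, but 0.0473 without Scrmbl 2, 0.0371 without siYap1/Wwtr1 3 and 0.0234 by edgeR), among them Itga11 (-2.29 ± 0.13). Wnt response genes rose in 4 and fell in 2 of 17 (adjusted p = 0.103, but 0.0476 without Scrmbl 3), Lgr6 by 2.26, and TGF-beta and BMP response genes rose in 5 and fell in 1 of 17 (0.103), with Bmp4 at -2.31. NF-kB genes rose in 1 and fell in 3 of 18 (0.293), Rho pathway genes rose in 3 and fell in 5 of 27 (0.261), and p53 target genes rose in 1 and fell in 1 of 15 (0.511), the riser being Cdkn1a (2.59 ± 0.18). Of the macrophage markers 0 of 5 passed (median 0.759, adjusted p = 0.198, but 0.0382 without siYap1/Wwtr1 3), and osteoblast markers rose in 3, Dmp1 by 4.32 ± 0.49, and fell in 1 (0.196). Adipocyte markers rose in 1 of 11 (0.299), endothelial markers in 1 of 10 (0.352), and LPA receptor and lipid phosphatase genes rose in 1 and fell in 1 of 10 (0.288). Treating the replicate numbers as pairs changed none of the list calls in this comparison.

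Do Rho inhibition and YAP/TAZ loss act on the same genes? These comparisons shared no library. Of 22096 genes tested in both, 1142 changed in both, and 94.5% of those moved the same way (Fisher's exact test, two-sided, p = 1.17e-229, genes not being independent). Higher in both were 656 genes (157 expected from n1 × n2 / N) and lower in both 423 (85.9 expected), against 35 higher in C3 and lower in the knockdown (117 expected) and 28 the other way (114 expected). Fold changes correlated across genes at r = 0.391. The shared count was 719 without Scrmbl 1 and 3055 with replicate number in both models. Shared members of lists included 17 cartilage genes that rose in both, 16 SRF/MRTF genes that fell in both, and 5 hypertrophic and 5 sulfated proteoglycan synthesis genes that rose in both. Other lists were mixed or small: in both, 3 fibrous genes rose, 6 fell and 1 moved apart, 4 immediate early genes rose, and 1 NF-kB gene rose while 2 moved apart. Of the cholesterol genes 2 fell and 1 moved apart, 3 cell cycle genes fell, 3 Rho pathway genes rose and 3 fell, and 3 TGF-beta and BMP genes rose, 1 fell and 1 moved apart. Focal adhesion genes rose in 1 and fell in 3, and YAP/TAZ targets rose in 1 and fell in 2. Wnt response genes rose in 2 and fell in 2, glycolysis and hypoxia genes rose in 2 with 1 that moved apart, and each list not named here had at most 1 shared gene in a direction. Of the 656 shared rises, 31 were higher, 89 lower and 536 not changed past the threshold in LPA. Among the 423 shared falls, 27 were higher, 47 lower and 349 not changed. Of all 22096 genes, 421 were higher and 744 lower in LPA. Against that proportion the shared rises leaned to falls in LPA, while the shared falls leaned neither way. C3 and LPA share the Ctrl libraries, which may affect these counts. Genes that moved apart, chosen after their values were seen, included Cxcl1 (3.69 ± 0.30 in C3 and -1.35 ± 0.25 in the knockdown, the latter not past the threshold without Scrmbl 1, at 0.0671), Sema3c (1.51 ± 0.12 and -1.82 ± 0.26) and Tnni1 (-1.51 ± 0.32 and 3.38 ± 0.33).

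LPA and the knockdown changed 346 genes in common, 35.3% of them the same way (Fisher's exact test, two-sided, p = 5.32e-06). Lower in LPA and higher in the knockdown were 161 (40.2 expected), higher in LPA and lower in the knockdown 63 (17.1), lower in both 80 (30.2) and higher in both 42 (22.7). The shared count was 179 without Ctrl 1, 215 without Ctrl 2, 588 without Ctrl 3, 206 without LPA 2, 180 without LPA 3, 227 without Scrmbl 1, and 1263 with replicate number in both models. It was 34 with all samples in one fit, 41.2% of them the same way, where the test did not pass (Fisher p = 0.714). Fold changes correlated across genes at r = -0.151.

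**Figure D3:**
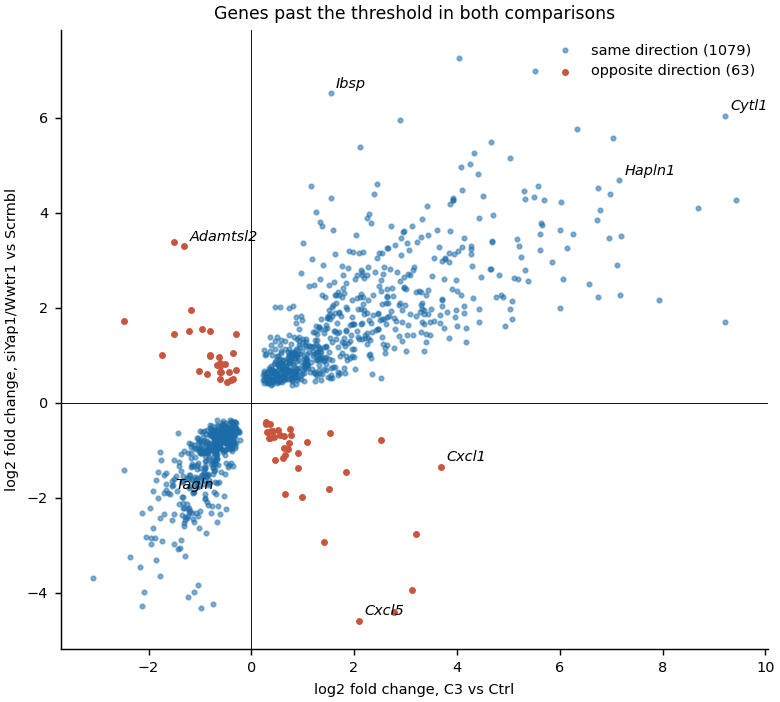
Log2 fold changes in C3 vs Ctrl (horizontal axis) and siYap1/Wwtr1 vs Scrmbl (vertical axis) for the 1142 genes past the threshold in both, 1 point per gene. Of these, 656 were higher and 423 lower in both, and 63 moved in opposite directions, such as Cxcl1.

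The substrate experiment set glass against stiff and soft gels. No gene passed the test in any of the 3 comparisons over 18511 genes. For Glass vs 5 kPa limma gave 0 (292 at an unadjusted p under 0.05, 20 higher and 272 lower on Glass) and edgeR 0. For 55 kPa vs 5 kPa limma gave 0 (7 unadjusted) and edgeR 0. For Glass vs 55 kPa limma gave 0 (136 unadjusted) and edgeR 0. Without 5 kPa 1 there were 3 genes in Glass vs 5 kPa, and without 55 kPa 2 there were 9 in 55 kPa vs 5 kPa. With replicate number in the model 7 genes passed in 55 kPa vs 5 kPa, all lower on 55 kPa. The 1 Glass library carries no known number: set under number 1, 843 genes passed in Glass vs 5 kPa and 186 in Glass vs 55 kPa, and under number 2, 8222 and 6535. In simulated data of this size, 0% of genes changed 4-fold were recovered in 55 kPa vs 5 kPa and in Glass vs 5 kPa by the model without replicate number, so such changes were not detectable with that model. The model with replicate number was not simulated. It leaves 1 residual degree of freedom, for the gels alone and with Glass under either number. With edgeR the median fold change was shifted by -0.157 in Glass vs 5 kPa, -0.184 in Glass vs 55 kPa and -0.008 in 55 kPa vs 5 kPa. EdgeR differed in scaling, model and genes tested (18039 against 18511), and their parts in the shift were not tested.

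Col2a1 was at 3530 reads on Glass, 32170 and 136300 on 55 kPa 1 and 2, and 94060 and 318900 on 5 kPa 1 and 2. In each number the 55 kPa library was thus below the 5 kPa library of the same number, and Glass was below all 4 gel libraries. Acan was ordered alike, at 356.6 on Glass, 1283 and 11320 on 55 kPa, and 2582 and 23670 on 5 kPa. Ankrd1 ran the other way, at 9865 on Glass, 4406 and 2281 on 55 kPa, and 2187 and 840.2 on 5 kPa. Sox9 was at 7420, at 8329 and 9355, and at 9419 and 13680 in the same order. Ccn1 was at 16960 on Glass, 12060 and 7646 on 55 kPa, and 11210 and 5208 on 5 kPa, and Ccn2 at 30600, at 44570 and 37900, and at 30560 and 23670. None of these passed the test (adjusted p = 0.999 for each in Glass vs 5 kPa).

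Glass was 1 library, so in every test against it the spread came from the gel libraries alone, and the lists are given as medians there without a call. Cartilage genes had a median of -2.77 in Glass vs 5 kPa and -1.84 in Glass vs 55 kPa (22 genes). In 55 kPa vs 5 kPa their median was -0.953 (camera adjusted p = 3.6e-06, and 0.664 with an estimated correlation). Within numbers, 55 kPa stood -0.844 below 5 kPa in number 1 (18 of 22 genes lower) and -1.06 in number 2 (21 of 22), and Glass stood -1.58 against 5 kPa 1 and -4.32 against 5 kPa 2. With replicate number in the model cartilage genes kept the 55 kPa vs 5 kPa call (camera adjusted p = 9.28e-14). That call was lost without 55 kPa 1 and its direction turned without 5 kPa 2. Leaving out 1 gel library leaves the replicate numbers unequal between the 2 gel groups. Fibrous matrix and tendon genes had a median of -1.55 in Glass vs 5 kPa, -1.12 and -1.80 against 5 kPa 1 and 2, and hypertrophic chondrocyte genes -1.35, at -1.28 and -1.49. Wnt response genes had -1.63, at -0.989 and -2.13, and cell cycle genes 0.624, at 0.478 and 0.874. In 55 kPa vs 5 kPa the fibrous, hypertrophic, Wnt response and cell cycle lists had camera calls. So did osteoblast marker, focal adhesion and stress response genes. All were lost with an estimated correlation and under some other settings. Within numbers 1 and 2, fibrous genes stood at -0.462 and -0.161 and hypertrophic genes at -0.837 and -0.246. Wnt response genes stood at -0.638 and -0.516 and cell cycle genes at 0.233 and 0.307. After a trend on gene length was removed, the Glass vs 5 kPa medians were -2.6 for cartilage, -1.1 for fibrous, -1.3 for hypertrophic, -1.48 for Wnt response and 0.816 for cell cycle genes, and focal adhesion genes went from -0.237 to 0.14. SRF/MRTF genes were 0.445 higher on 55 kPa than on 5 kPa (adjusted p = 0.000131, and 0.664 with an estimated correlation, 0.425 and 0.473 within numbers). This call was lost without 55 kPa 1 (0.118), 55 kPa 2 (0.102) or 5 kPa 2 (0.343). Ribosomal protein genes were 0.602 higher on 55 kPa (adjusted p = 8.98e-07, and 0.664 with an estimated correlation, 0.885 and 0.333 within numbers). Of 28 members, 0 were lower on 55 kPa in number 1 and 0 in number 2. With replicate number in the model camera adjusted p was 6.62e-20, from the same fit and with the same limits as for cartilage genes. The direction turned without 55 kPa 1 and without 5 kPa 2. YAP/TAZ targets (21 genes) did not share the order of Ankrd1, as their medians differed in sign between the numbers. For 55 kPa against 5 kPa they stood at -0.104 in number 1 and 0.237 in number 2. Glass stood at 0.284 against 5 kPa 1 and at -0.391 against 5 kPa 2. Immediate early and skeletal muscle marker genes had a median above 0 and a mean below it in Glass vs 5 kPa. Of the genes higher in the knockdown, 66.4% of 1061 were lower on Glass than in both 5 kPa libraries, against 30.1% of all 18292, and 57.0% were lower on 55 kPa in both numbers, against 26.8%. Of 855 genes lower in the knockdown, 30.9% were lower on Glass than in both 5 kPa libraries. On 55 kPa 17.3% of them were lower and 44.1% higher in both numbers. For 2538 genes higher in C3 the shares were 48.3% and 41.8%, against 29.9% and 26.7% of all 18403, and for 2078 genes lower in C3 they were 26.8% and 19.5%. For 707 genes lower in LPA the shares were 63.9% and 49.6%, and for 416 genes higher in LPA 26.4% and 19.5%. High shares were thus held by genes that rose in C3 or the knockdown and by genes that fell in LPA. Those sets overlap, with 161 genes lower in LPA and higher in the knockdown (40.2 expected). In the sets of opposite direction the shares were near or below those of all genes. The fold changes of Glass vs 5 kPa correlated across genes at r = -0.264 with those of the knockdown (-0.182 without 5 kPa 2 and -0.19 with Glass under number 1). With those of C3 they correlated at r = -0.234 (-0.106 and -0.11 in the same order). As no gene passed in Glass vs 5 kPa by limma or edgeR, the count of shared genes could only be 0 and says nothing about sharing.

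**Figure D4:**
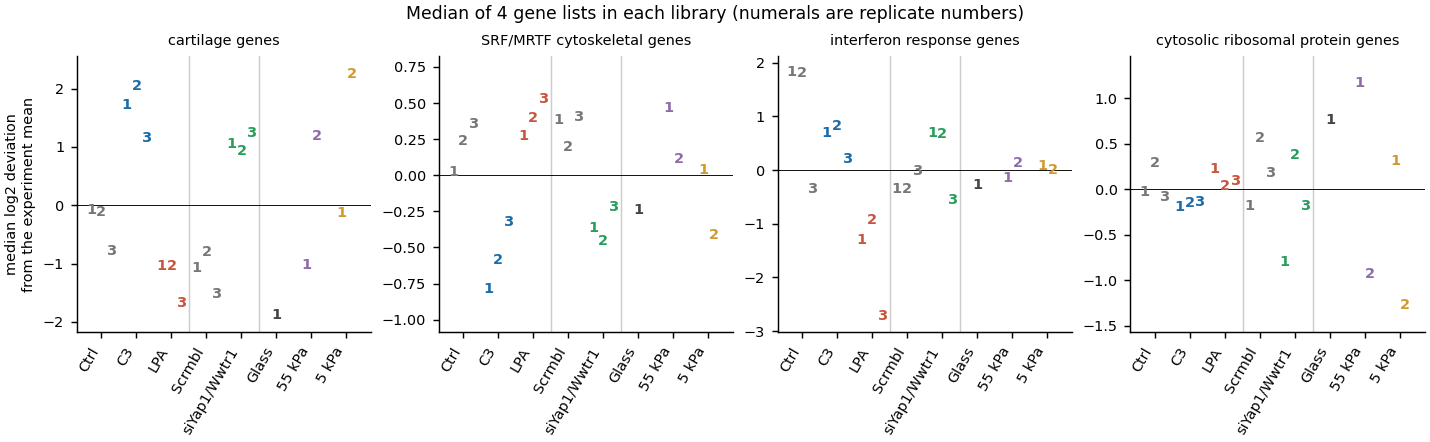
Median log2 deviation from the experiment mean of 4 gene lists in each library, on a linear axis, with numerals giving replicate numbers. Interferon response genes stood at 1.82 and 1.80 in Ctrl 1 and 2 and at -0.35 in Ctrl 3, and the substrate libraries of number 1 and 2 stood apart in ribosomal protein genes.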

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

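Tests with edgeR and with Glass counted as 2 libraries were chosen only after the result was seen. Except where a construction is named, the cause of a change was not tested. The number of genes changed in C3 vs Ctrl (5158) was 1221 with all samples in 1 fit, which also tested 18534 genes where the separate fit tested 23475. For LPA vs Ctrl (1168) it was 2424 with replicate number in the model, 705 with only the 2 groups, 111 with all samples in 1 fit, and 469 (without LPA 3) to 2619 (without Ctrl 3) when 1 library was left out. For C3 vs LPA (6235) it was 1920 with all samples in 1 fit. For siYap1/Wwtr1 vs Scrmbl (2127) it was 6260 with replicate number in the model, 978 with all samples in 1 fit, and 1153 (without Scrmbl 1) to 1710 when 1 library was left out. Named genes lost calls with all samples in 1 fit too. The losses were 45 of 98 in C3 vs Ctrl, 51 of 67 in LPA vs Ctrl, 27 of 110 in C3 vs LPA and 31 of 87 in siYap1/Wwtr1 vs Scrmbl. Calls gained were 0, 2, 0 and 1 in the same order.

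For Glass vs 5 kPa (0) the count was 843 with Glass under number 1, 8222 under number 2, 59 with only the 2 groups, 1011 with all samples in 1 fit, and 0 to 3 (without 5 kPa 1) when 1 library was left out. For 55 kPa vs 5 kPa (0) it was 7 with replicate number in the model and 0 to 9 (without 55 kPa 2) when 1 library was left out. For Glass vs 55 kPa (0) it was 186 and 6535 with Glass under number 1 and 2, and 189 with all samples in 1 fit. The limma counts at an unadjusted p under 0.05 were 292, 7 and 136, and edgeR gave 0 in each.

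In the Ctrl, C3 and LPA experiment every library correlated best with a library of its own number, at 0.0342 to 0.104 between same-numbered libraries. The main fit was left unpaired, as the plan fixed for every experiment. With replicate number in the model C3 vs Ctrl had 6353 genes, LPA vs Ctrl 2424 and C3 vs LPA 7355.

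All 78 gene list calls at the preset correlation, 20 of them in comparisons with the single Glass library, were lost with an estimated correlation, which left 0. The correlation of C3 and LPA fold changes (0.169) was 0.284 with a pseudocount of 0.1, 0.0525 by edgeR, 0.103 with all samples in 1 fit, and 0.142 to 0.263 (without Ctrl 3) when 1 library was left out. Genes changed in both C3 and the knockdown (1142) were 3055 with replicate number in the model, 373 with all samples in 1 fit, and 719 (without Scrmbl 1) to 1108 when 1 library was left out. For LPA and the knockdown (346) they were 1263, 225 with only the 2 groups, 34 with all samples in 1 fit, and 179 (without Ctrl 1) to 588 (without Ctrl 3). For Glass vs 5 kPa and the knockdown (0) they were 258 and 1053 with Glass under number 1 and 2 in its own model alone, 522 with replicate number in both models and Glass under number 1, 43 with only the 2 groups, 197 with all samples in 1 fit and 2 without 5 kPa 1. For Glass vs 5 kPa and C3 (0) they were 375, 2499, 483, 35, 184 and 2 in the same order.

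With an adjusted p under 0.05 on at least 1 side, directions turned in 15 settings of list results, 6 of them in comparisons with the single Glass library, and in 2 genes. Turns without a call on either side are left out of these counts. Without 1 gel library, 55 kPa and 5 kPa no longer hold the same replicate numbers, by which these libraries parted. Glass has no spread of its own and its number is unknown, and without 1 gel library of a group it stands as 1 library against 1, so its adjusted p-values are printed without a call and only the sign is read. In Glass vs 5 kPa NF-kB inflammatory genes had a lower sign with Glass under number 1 (0.000653) and without 5 kPa 2 (0.005), and a higher one without 5 kPa 1 (0.00179). In 55 kPa vs 5 kPa cartilage genes turned without 5 kPa 2 (0.509, range when 1 library was left out 2.95e-12 to 0.972 without 55 kPa 1), and fibrous genes without 55 kPa 1 (0.44, range 0.0135 to 0.944 without 5 kPa 2). Focal adhesion genes turned without 55 kPa 2 (0.93, range 0.00307 to 0.93, and 0.911 and 0.104 without 5 kPa 1 and 2), and NF-kB genes without 55 kPa 2 (0.0187) and 5 kPa 1 (6.92e-05, range 2.06e-06 to 0.0187). Stress response genes turned without 55 kPa 1 (0.324) and 5 kPa 2 (0.39, range 0.00206 to 0.39), and ribosomal genes without 55 kPa 1 (0.000316) and 5 kPa 2 (0.39, range 1.06e-14 to 0.39). In Glass vs 55 kPa NF-kB (2.08e-05), stress response (0.00242) and ribosomal genes (0.00247) changed sign with Glass under number 1, and ribosomal genes without 55 kPa 2 (0.0391, and 3.56e-12 in the first direction without 55 kPa 1). Fn1 in C3 vs LPA was at 0.00 under quantile normalisation, which by construction gives the top-ranked gene, Fn1 in every library, the same value. Postn in LPA vs Ctrl was at 0.00 as well, and the cause was not tested.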

Other observations

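The tests of the interferon response and of a batch in the substrate libraries were chosen only after the result was seen. Interferon response genes were lower in LPA than in Ctrl in every number, with medians of -3.28, -2.65 and -2.13 over 24 genes. Each number holds 1 LPA and 1 Ctrl library, so a batch shared by same-numbered libraries falls on both groups alike. Within each number all 24 genes were lower in LPA. A batch that falls on both groups alike could not make a group difference whatever the values were, so these medians do not test it. The deepest LPA library held 5.9 M more reads than the deepest Ctrl library, so the LPA libraries were not shallower throughout. Without 1 library the list median was at most -2.18, so no single library made the difference. The cause of the lower interferon response is left open. Over all tested genes Ctrl 3 correlated with Ctrl 1 and Ctrl 2 at 0.983 and 0.982, about as those 2 did with each other (0.984). It stood apart from them on the principal components. On the first principal component (42.9% of the variance) it was at 55.59, beside LPA 1 and LPA 2 (56.62 and 53.88), with Ctrl 1 and Ctrl 2 at 28.64 and 28.9. On the second (13.9%) it was at 20.57, between Ctrl 1 and Ctrl 2 (53.91 and 75.23) and LPA 1 and LPA 2 (-26.5 and -27.48). On the first component the number 3 libraries of the other groups were shifted the same way. C3 3 was at -79.9, against -111.4 and -106.8 in C3 1 and C3 2, and LPA 3 was at 74.51. The shift on that component was thus not particular to Ctrl 3. What set Ctrl 1 and Ctrl 2 apart from Ctrl 3 was not tested.

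The substrate libraries parted by replicate number: the deviations of 55 kPa and 5 kPa libraries with the same number correlated at 0.741 across genes. With 2 pairs and centred values this correlation is shared by both pairs. After every library was thinned to the lowest depth it was 0.748, and after a trend on gene length was removed it was 0.72, so neither accounted for all of it. Gene length was related to the split: number 2 minus number 1 correlated with it at a Spearman rho of 0.362, with a median of -0.685 in the shortest 25% of genes and 0.921 in the longest 25%. A batch shared by libraries of the same number may account for it, and differences between separate cultures remain untested. The first principal component, 68.2% of the variance, held number 1 and Glass on one side and number 2 on the other, so Glass may differ from number 2 by batch as well as by substrate.

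For each comparison of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. The real split and the highest of the others gave 5158 and 0 genes in C3 vs Ctrl, 1168 and 1 in LPA vs Ctrl, 6235 and 0 in C3 vs LPA, and 2127 and 0 in siYap1/Wwtr1 vs Scrmbl, so 1 split in each had as many genes as the real one, itself. For lists they gave 9 and 9 in C3 vs Ctrl, 13 and 11 in LPA vs Ctrl, 12 and 10 in C3 vs LPA, and 14 and 11 in siYap1/Wwtr1 vs Scrmbl. In C3 vs Ctrl 3 splits had 9 lists. In the knockdown the splits that part all 3 pairs, as the real one does, gave 0 genes each and 8, 10 and 6 lists.

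The authors' deposited DESeq2 results have 4911 genes with an adjusted p under 0.05 in C3 vs Ctrl (2836 higher), 1633 in LPA vs Ctrl (598 higher), 2987 in siYap1/Wwtr1 vs Scrmbl (1627 higher), 126 in 55 kPa vs Glass (121 higher) and 834 in 5 kPa vs Glass (767 higher). The substrate counts came from tables in which the Glass library stands as 2 samples.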
